A study of Mus musculus with 12 samples.

How the data were processed

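Androgen receptor (AR) binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in prostate tissue of 3 wild-type mice and in prostate tumours of 3 mice with an activating deletion in Ctnnb1, the gene of beta-catenin, and loss of a copy of the tumour suppressor Pten. All mice were 9 months old. Each of the 6 AR libraries had an input library from the same mouse, so the series holds 12 libraries. Per the labels, the mice of each tissue were independent animals. Groups and mouse numbers were taken from the sample titles.

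The deposited table lists 3988 genomic regions with coordinates in GRCm38, the build named in the submitters' processing notes. The notes also name FastQC 0.10.1, TopHat2 2.0.10 and Bowtie2 2.1.0.0 without giving their roles. Per the file headers, peaks were called in each mouse separately by 2 callers, USeq and MACS 1.4. The caller thresholds, the control behind each fold, the way peaks were merged into regions and whether coordinates count from 0 or from 1 are not given in the sources used here. Coordinates are given as in the table. Where a caller found a peak in a mouse, the deposited table gives the caller's fold (a linear ratio) for that mouse, and otherwise the cell is empty. Folds of single mice are therefore the authors' values. Mean folds, medians and SDs of merged loci were computed from them, and the authors' own mean folds are named as theirs. The authors marked a tissue as having a peak where at least 2 of its 3 mice had a call by the same caller. Recomputed from the calls, this rule gave the authors' marks in all 3988 rows for both tissues. The authors' mean fold of a marked tissue equalled the mean of its call folds, within 0.006, in all 286 rows marked in tumour and all 3819 rows marked in wild type. The deposited table further gives a score per region, the larger mean fold as a percent of the smaller where both tissues were marked. Every region in the table is marked as different, and each is marked as a peak in wild type, in tumour or in both. Calls in single mice are therefore listed only at regions that were reproducible in a tissue. The lowest score among the 117 rows marked in both tissues was 110%, so regions marked in both tissues with folds within 10% of each other are absent. The row index runs to 28899, so 24911 index values are not in the table. Numbers and overlaps of peaks therefore describe a list chosen for difference between the tissues and not all AR binding. The table holds no read counts, so the depth per library is unknown, and intervals on shares cover counting error over loci only. A fold from a peak caller can also depend on the depth of the library and of its control.

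Rows that overlapped by at least 1 bp were merged into 3451 loci, because 489 loci were split over 2 rows and 24 over 3 rows, often with one row per tissue. A locus took the calls of all its rows and, per mouse and caller, the highest fold. A locus was called reproducible in a tissue by the authors' own rule. Before the data were examined, the plan had been to count a peak of any mouse. The authors' rule was used as the main definition once the table was seen to carry it, and the count over any mouse is printed beside it. The mean fold of a locus in a tissue is the mean over all its calls of both callers. MACS folds are given with their SD over mice and the number of mice (n) with a MACS call.

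The number of loci called per mouse was compared between tissues with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 mice against 3. Expected overlap came from 100 reshuffles of the tumour loci over their own chromosomes. No test was run per locus: the table holds the callers' own folds, only where a peak was called, and the plan was to describe such values without a test. At loci reproducible in both tissues, the difference of mean log2 MACS folds was taken where each tissue had a MACS fold in at least 2 mice. MACS was put first after the data were seen, because its folds correlated better between wild-type mice (Spearman's rho across loci 0.47 to 0.62, against 0.17 to 0.22 for USeq).

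Each locus was assigned to the nearest protein-coding gene body of the RefSeq annotation of GRCm38.p6, within 50 kb, with ties kept. That table gives gene spans without strand or exons, so distances to transcription starts and shares in promoters, exons and introns, which had been planned, are not given here. No genome sequence was used, so the planned motif search was not run. The gene symbols in the deposited table were not used for assignment, because 421 of the 2461 rows with a matched gene (17.1%) lay over 5 kb from the gene named. Shares of loci in gene bodies, within 1 kb of one, or farther, and shares of loci per chromosome, were compared between tumour loci and loci found in wild type alone with two-sided Fisher's exact tests and Benjamini-Hochberg (BH) adjustment. Intervals are 95% Clopper-Pearson intervals. Gene-body shares were also set beside 100 reshuffles. Loci are not replicate mice, so these tests describe the lists. Folds and widths were compared between classes of loci by two-sided permutation tests of the difference in medians with 100000 permutations.

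Before the data were examined, 15 gene lists were fixed. Of their 231 entries, 229 matched a protein-coding gene. The share of a list's genes with a locus was compared with all other protein-coding genes by a two-sided Fisher's exact test with BH adjustment over the 15 lists. After the data were seen, a second test was added that draws random genes (10000 draws) with a similar territory, meaning the stretch of genome for which a gene is the nearest. Long or isolated genes collect more loci by chance. On 20 simulated sets of random loci, Fisher's exact test called the AR cofactor list 3 times and the matched test 0 times. With loci planted at AR target genes, both tests called that list in 20 of 20 sets. A gene-body share set 10 points lower in tumour was called in 47 of 50 simulated sets, a doubled share of chromosome 8 in 25 of 50, and a median fold set 1 higher in 49 of 50.

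The genes named are those next to the 10 loci with the highest mean fold in each class (both tissues, wild type alone, tumour alone), up to 4 genes per list by their highest fold, and 10 genes fixed beforehand (Pbsn, Fkbp5, Nkx3-1, Tmprss2, Ar, Axin2, Lgr5, Myc, Pten and Ctnnb1). Per1, Pmepa1, Tcf7, Tcf7l2, Pik3r1, Defb43, Creld2, Mthfd2 and Pitpnm2 are named in the report outside this rule and were chosen after their values were seen. Alternatives covered a stricter fold limit, other overlap rules, each mouse left out, the width of loci, other distances to genes, mouse number as a block, and, chosen after seeing the data, USeq folds, unmerged rows, the territory-matched test, the location test without tumour-only loci, and strength and width at loci of a single row. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.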

Results

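AR binding was compared between prostate tumours of mice with activated beta-catenin and loss of a copy of Pten, and age-matched wild-type prostate. The aim was to ask where the receptor binds in tumours relative to normal tissue. No group carried either genetic change alone, so the effects of these changes cannot be told apart. AR, a nuclear hormone receptor, drives the secretory programme of the prostate epithelium. Beta-catenin is the transcriptional effector of Wnt signalling. Peaks had been called by the authors in 3 tumours and 3 wild-type prostates, each from a separate mouse. The 3988 regions of the authors' table were merged into 3451 loci. The regions had been kept by the authors because they differed between the tissues, and the sequencing depth of the libraries is unknown.

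Most listed AR loci were found in wild-type prostate and few in tumour. By the rule of at least 2 mice with the same caller, 3408 loci were reproducible in wild type and 284 in tumour, a 12-fold difference. Of the tumour loci, 241 (84.9%, 95% interval 80.2 to 88.8%) were also reproducible in wild type. Of the wild-type loci, 7.07% (6.23 to 7.98%) were also reproducible in tumour. Leaving out single mice, these shares ran from 56.5 to 90.3% and from 0.675 to 12.5%. With a mouse left out, both remaining mice of its tissue had to have a call by the same caller, a stricter rule. Reshuffled positions gave a mean of 0.72 shared loci and at most 3. A total of 3167 loci were reproducible in wild type alone and 43 in tumour alone. Counting a call in any mouse, 690 loci had a tumour call and 3439 a wild-type call, and 678 had both. Regions reproducible in neither tissue are not listed. A call in a single tumour could thus appear only at a locus reproducible in a tissue, so this overlap is largely set by the filter.

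The 3 tumours had 593, 54 and 364 loci called by either caller, with a mean of 337 ± 271 (SD, n = 3). The 3 wild-type prostates had 3154, 3157 and 1936, with a mean of 2749 ± 704 (SD, n = 3). The wild-type mean was 8.16 times the tumour mean, and every wild-type mouse had more loci than every tumour. These counts cover listed loci only, each reproducible in a tissue, and 3167 of the 3451 were reproducible in wild type alone. Calls of a single mouse elsewhere are not listed, so the ratio depends on this filter. Leaving out single mice, the ratio of means ran from 5.63 to 14.5. The two-sided exact permutation test gave p = 0.1, the smallest that 3 mice against 3 allow. The reproducible tumour set rested on tumour mice 1 and 3, which shared 259 loci by the same caller, while mice 1 and 2 shared 46 and mice 2 and 3 shared 27. The ratio of wild-type to tumour loci was 126 without tumour mouse 1, 74.1 without tumour mouse 3, 5.47 without wild-type mouse 1 and 5.52 without wild-type mouse 2. These ratios set a tissue called in 2 of 2 mice against one called in 2 of 3. The effects of the stricter rule and of the mouse left out cannot be told apart.

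**Figure D1:**
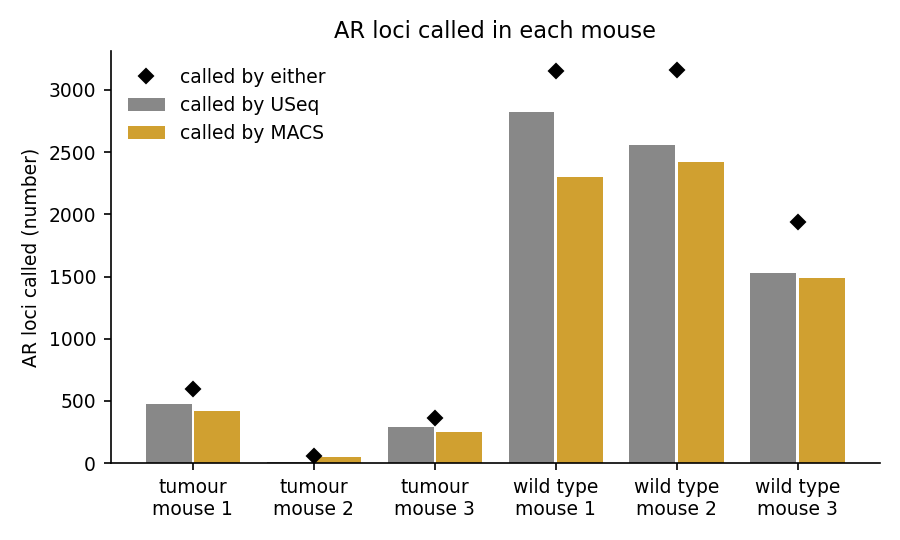
Number of listed AR loci called in each of the 6 mice, by USeq (grey bars), by MACS (yellow bars) and by either caller (diamonds). Each listed locus was reproducible in wild type, in tumour or in both. The 3 tumours lie between 54 and 593 loci by either caller and the 3 wild-type prostates between 1936 and 3157.

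At loci bound in both tissues, MACS fold enrichment was lower in tumour. Among 164 shared loci with MACS folds in at least 2 mice of each tissue, the median log2 difference of tumour minus wild type was -0.90 (quartiles -1.35 and -0.55), a tumour fold of 0.535 times wild type. The tumour fold was the lower at 160 loci and the higher at 4. Median log2 deviations from the wild-type mean were -0.80, -0.86 and -1.03 in tumour mice 1, 2 and 3, with mouse 2 represented at 27 loci. They were 0.00, 0.11 and -0.05 in the wild-type mice. USeq folds differed less: the median was -0.41 over 171 loci, with 126 lower and 45 higher in tumour. In the authors' deposited table, the mean fold was lower in tumour in 102 of the 117 regions marked in both tissues. Over all loci called in a mouse, the median MACS fold was 7.61 ± 2.68 (SD, n = 3) in tumours and 11.06 ± 0.23 (SD, n = 3) in wild type (exact permutation p = 0.1, two-sided), whereas the median USeq fold was 8.44 ± 1.29 (SD, n = 3) and 8.81 ± 0.86 (SD, n = 3; exact permutation p = 0.8).

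**Figure D2:**
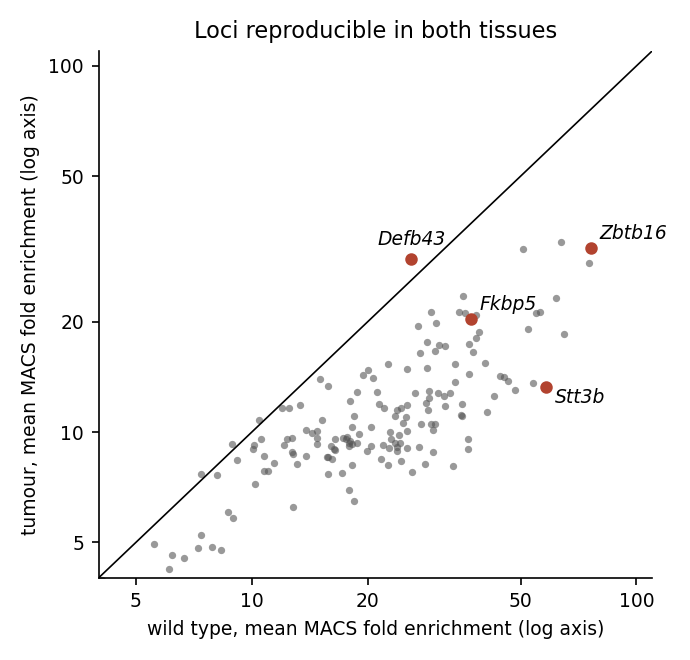
Mean MACS fold enrichment in tumour (vertical) against wild type (horizontal), both on log axes, at 164 loci reproducible in both tissues. The line marks equal folds. By mean log2 fold the tumour was lower at 160 loci, Stt3b having the largest difference, and higher at 4, led by Defb43.

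The strongest shared locus was inside Zbtb16 (chromosome 9, 48723242 to 48724420), which encodes an androgen-induced zinc-finger transcription factor. Its MACS fold was 31.9 ± 18.8 (SD, n = 3) in tumour and 76.4 ± 14.1 (SD, n = 3) in wild type, while its USeq folds were 26.4 ± 16.5 (SD, n = 3) and 23.9 ± 1.28 (SD, n = 3). Zbtb16 held more wild-type loci than any other gene, 12, of which 4 were also reproducible in tumour. A locus inside Rcn1, a calcium-binding protein of the endoplasmic reticulum (chromosome 2, 105396740 to 105397689), had MACS folds of 28.9 ± 17.2 (SD, n = 3) in tumour and 75.4 ± 7.66 (SD, n = 3) in wild type, and USeq folds of 17.97 ± 10.12 (SD, n = 3) and 18.5 ± 0.53 (SD, n = 3). Next came loci inside the transcription factor gene Klf13 and, 17424 bp from Armc12, a locus of chromosome 17 that lies 26007 bp beyond the Fkbp5 gene body. Those nearest to Trpm3 (61149 bp), Lpin1 (inside), Piwil4 (11703 bp), Stt3b (22297 bp), Ptpn1 (85530 bp) and Sort1 (inside) completed the 10. The rank of Sort1 depends on unstable wild-type USeq folds, 61.1 ± 88.3 (SD, n = 3). Its wild-type MACS folds were 22.5 ± 4.68 (SD, n = 3). The locus near Stt3b had the largest difference of all 164, with MACS folds of 13.3 ± 0.58 (SD, n = 2) in tumour and 58.2 ± 16 (SD, n = 3) in wild type.

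The strongest loci reproducible in wild type alone lay inside Wars (tryptophanyl-tRNA synthetase), Adgrv1, Hif3a (a hypoxia-inducible factor subunit), Cadps2, Kctd19, Galnt18, Nek7 and Nfkb1 (an NF-kappaB subunit), 15669 bp from Atp11a and 115458 bp from Usp24. The strongest locus in Nfkb1 (chromosome 3, 135647353 to 135648290) had a MACS fold of 46.4 ± 9.41 (SD, n = 3) in wild type and no call in any tumour. Another locus in Nfkb1 (135631620 to 135632512) was reproducible in both tissues, with MACS folds of 11.7 ± 2.00 (SD, n = 2) in tumour and 12.5 ± 7.96 (SD, n = 2) in wild type. The locus in Hif3a (chromosome 7, 17057854 to 17058744) had 51.5 ± 19 (SD, n = 2) and likewise no tumour call. Wars, Usp24 and Cadps2 each had a call in a single tumour. At Wars the USeq folds of the wild-type mice were 78.8 ± 115 (SD, n = 3), so its rank depends on an unstable value. Other ranks were unstable too. In wild type, USeq folds were 38.4 ± 42.5 (SD, n = 2) at Adgrv1 and 54.3 ± 45.7 (SD, n = 3) at Cadps2. Galnt18 had no MACS call and USeq folds of 36.1 ± 40.1 (SD, n = 2). At Atp11a a single wild-type mouse had a USeq fold of 87, against MACS folds of 15.5 ± 2.40 (SD, n = 2). Kctd19 had a MACS call in a single wild-type mouse, with a fold of 12.2.

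The 43 loci reproducible in tumour alone were weak. Their mean fold had a median of 4.80, against 10.3 at wild-type-only loci and 9.48 (tumour fold) at shared loci (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations give, BH p = 1.25e-05). In 31 of them 1 wild-type mouse also had a call, and 12 had no wild-type call. Tumour mouse 2, with the fewest calls, had a call at 21 of them (48.8%) and at 28 of the 241 shared loci (11.6%). The 10 strongest lay inside Myo5b (a vesicle motor), Tmod3, Xpo7, Zfp280d, Myof, Kmt2a (a histone methyltransferase) and Ttc23, and near Csf2ra (17164 bp), Tcim (45394 bp) and Cnn3 (477 bp). Those at Tmod3, Kmt2a, Ttc23, Csf2ra, Tcim and Cnn3 also had a call in a single wild-type mouse. There the mean fold was higher in wild type than in tumour at Tmod3 (17.6 against 14.2), Ttc23 (11.3 against 10.2), Csf2ra (10.8 against 10.2) and Tcim (12.1 against 9.83). It was lower in wild type at Kmt2a and Cnn3. The locus in Myo5b (chromosome 18, 74483136 to 74483520) had USeq folds of 34.6 ± 18.8 (SD, n = 2), a MACS fold of 8.94 in a single tumour and no wild-type call.

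Among listed loci, wild-type strength went with detection in tumour. Shared regions with folds within 10% of each other are not listed, which can affect these comparisons. Loci also reproducible in tumour had a median wild-type fold of 15.6 (quartiles 11 and 21.6, 241 loci), against 10.3 (8.58 and 13.3, 3167 loci) at wild-type-only loci (permutation p = 1e-05, the smallest possible, BH p = 1.25e-05). They were also wider, with medians of 892 and 725 bp (permutation p = 1e-05, BH p = 1.25e-05), a difference of 167 bp to which the merging of regions can add. Among loci of a single region the differences were 156 bp and 3.79 in fold (permutation p = 0.0001 for each, the smallest that 10000 permutations give). The difference in fold, 5.28, was 0.80 without tumour mouse 3 (permutation p = 0.342) and 1.98 without tumour mouse 1 (permutation p = 0.0442), where the difference in width was 330 bp. Among wild-type loci ranked by fold, 43.1% (37.8 to 48.6%) of the top 10% had a call in at least 1 tumour. With 10 groups of equal size, the lowest share, 8.21% (5.53 to 11.6%), was in group 3 from the weakest, and the weakest group had 15.5% (11.9 to 19.8%).

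**Figure D3:**
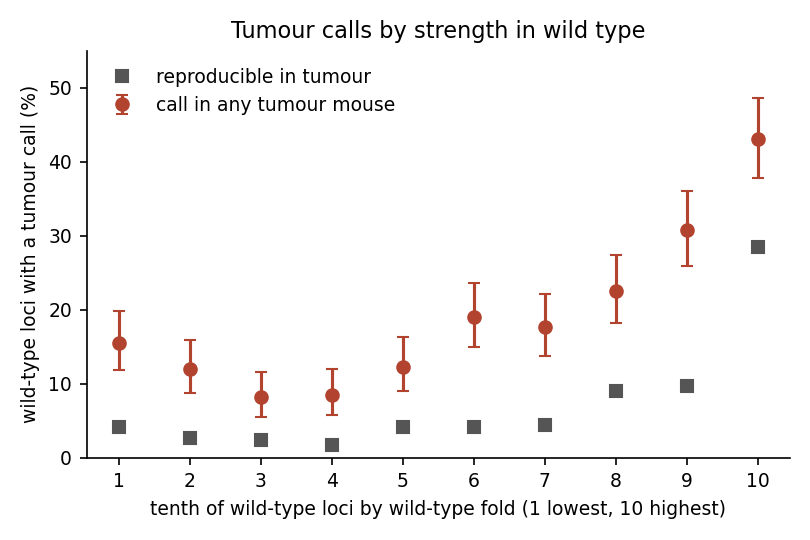
Share of wild-type loci with a call in any tumour mouse (red circles, with 95% Clopper-Pearson intervals) and share reproducible in tumour (grey squares), in 10 groups of 340 or 341 loci ranked by wild-type fold. The circles run from 8.21% in group 3 to 43.1% in the strongest group.

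Genes known to be targets of AR in prostate were bound far more often than other genes, in both tissues. In wild type, 18 of 33 (54.5%, 36.4 to 71.9%) had a locus, against 9.77% of other protein-coding genes (Fisher's exact test, BH p = 2.56e-09; territory-matched BH p = 0.003). In tumour, 5 of 33 (15.2%, 5.11 to 31.9%) had a locus, against 0.938% of others (Fisher's exact test, BH p = 0.000222; territory-matched BH p = 0.003). The tumour share was 6.06% without tumour mouse 1 (Fisher's exact test, BH p = 0.00556) and without tumour mouse 3 (BH p = 0.018). The 5 genes were Zbtb16, Fkbp5, Cdkn1a (the cell cycle inhibitor p21), Per1 (a circadian clock gene) and Pmepa1. Fkbp5, a co-chaperone of steroid receptors, had 4 wild-type loci, and 2 without wild-type mouse 1 or 2. Its strongest (chromosome 17, 28419566 to 28420750) had a MACS fold of 20.4 ± 2.31 (SD, n = 2) in tumour and 37.2 ± 16.7 (SD, n = 2) in wild type, and was its only reproducible tumour locus. Cdkn1a (chromosome 17, 29094226 to 29095189) had 15.4 ± 8.19 (SD, n = 3) and 33.7 ± 5.54 (SD, n = 2), while USeq gave 27.4 in a single tumour and 14 ± 0.78 (SD, n = 3) in wild type. Hpgd, a prostaglandin-degrading enzyme, was bound in wild type alone at its strongest locus (34.8 ± 12.4, SD, n = 3). Tmprss2, a serine protease gene, had 4 wild-type loci inside its gene body and no tumour call. Nkx3-1, a prostate homeobox gene, had 1 wild-type locus at 22716 bp and no tumour call, and Pbsn, the probasin gene, had no locus within 50 kb. Of the 43 wild-type loci at AR target genes, 8 (18.6%) were reproducible in tumour, against 6.92% of other wild-type loci (Fisher's exact test, p = 0.00924), but this difference did not pass adjustment over the 15 lists (BH p = 0.139).

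**Figure D4:**
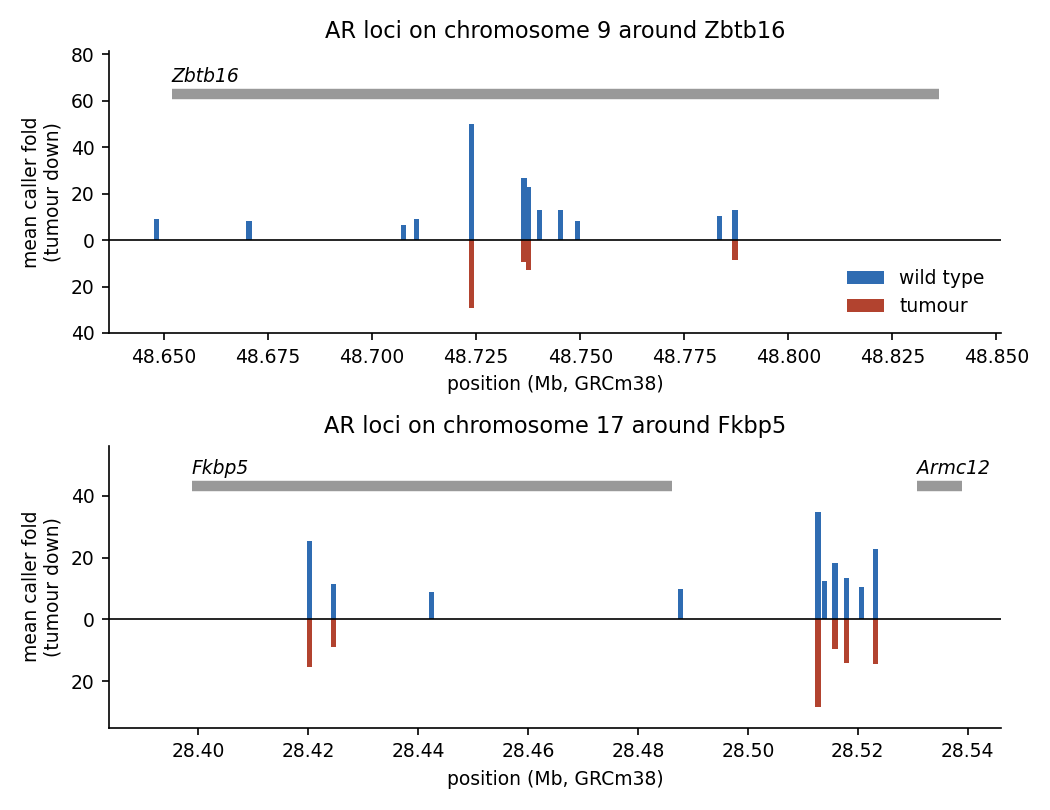
Mean caller fold (both callers, all mice with a call) of AR loci in wild type (blue, upwards) and tumour (red, downwards) along chromosome 9 around Zbtb16 and chromosome 17 around Fkbp5 and Armc12, with gene bodies in grey and positions in Mb of GRCm38. Zbtb16 has 12 wild-type loci, and the strongest reaches 50.2 in wild type and 29.2 in tumour.

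Genes of AR and its cofactors were bound in wild type in 10 of 22 cases (45.5%, 24.4 to 67.8%, Fisher's exact test, BH p = 0.000133; 27.3% without wild-type mouse 2), which did not pass when genes of similar territory were drawn (BH p = 0.072). They included Nr3c2 (the mineralocorticoid receptor), Grhl2, Erg, Foxa1 and Ar itself, at 24152 bp from the gene body, a locus not reproducible without wild-type mouse 3. Grhl2 was the only member with a reproducible tumour locus. Endothelial markers had a wild-type locus in 4 of 7 cases (57.1%, 18.4 to 90.1%, Fisher's exact test, BH p = 0.0128): Erg, Cdh5, Vwf and Pecam1. That call did not hold with territory-matched genes (permutation, BH p = 0.319), without wild-type mouse 2 (Fisher's exact test, BH p = 0.184) or in the stronger 50% of regions (BH p = 0.208). Erg is a member of both lists.

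Wnt and beta-catenin target genes, the programme downstream of the activated beta-catenin in the tumour genotype, had a wild-type locus in 6 of 26 cases (23.1%, 8.97 to 43.6%, Fisher's exact test, BH p = 0.111) and a tumour locus in 0 of 26, where the interval reaches 13.2%. The locus closest to Axin2, at 43114 bp, was of wild type alone and was assigned to another gene. Beyond the 50 kb limit, loci reproducible in both tissues lay 60522 bp from Axin2 and 85901 bp from Myc. The former was weak, with MACS folds of 4.61 ± 0.59 (SD, n = 3) in tumour and 6.22 ± 1.95 (SD, n = 3) in wild type. Its mean USeq folds were 2.00 and 2.44. MACS called it in all 6 mice at these low folds, and no list of regions with signal in any library was used here. Whether it is a site of AR binding therefore cannot be told. The locus 85901 bp from Myc had MACS folds of 8.12 ± 2.19 (SD, n = 2) in tumour and 18.25 ± 3.98 (SD, n = 3) in wild type. The 6 genes of the list with a wild-type locus were Nkd1 (chromosome 8, 4347 bp from the gene, MACS fold 16.9 ± 5.66, SD, n = 3), Fzd7, Sox9, Myc, Tcf7 and Tcf7l2. The locus near Myc lay 26704 bp from the gene and was not reproducible without wild-type mouse 1 or 2. Axin2, Lgr5, Pten and Ctnnb1 were not the nearest gene of any locus within 50 kb. In the PI3K and AKT pathway, 5 of 19 genes had a wild-type locus (26.3%, 9.15 to 51.2%, Fisher's exact test, BH p = 0.111), namely Igf1r, Foxo3, Irs1, Mtor and Pik3r1. Foxo3 and Irs1 also had a tumour locus (2 of 19, 10.5%, Fisher's exact test, BH p = 0.106). At Foxo3 the MACS fold was 9.08 ± 3.57 (SD, n = 2) in tumour and 25.4 ± 4.43 (SD, n = 3) in wild type. At Irs1 it was 8.14 ± 2.17 (SD, n = 2) and 22.6 ± 10.1 (SD, n = 3).

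No other list passed the test in either tissue. Luminal epithelial markers had a wild-type locus in 3 of 11 cases (Cdh1, Foxa1 and Nkx3-1, Fisher's exact test, BH p = 0.215), basal markers in 2 of 8 (Trp63 and Itga6, BH p = 0.342), and seminal vesicle secretory genes in 2 of 8 (Svs6 and Svs3b, BH p = 0.342). There was 1 gene each for neuroendocrine markers (Ncam1, of 9), DNA repair (Rad51b, of 14), steroid hormone metabolism (Hsd17b3, of 13) and stromal and smooth muscle markers (Dcn, of 13). Cell cycle genes (16), immune cell markers (14) and squamous markers (14) had none. In tumour, Svs3b was the only gene of these lists with a reproducible locus.

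**Figure D5:**
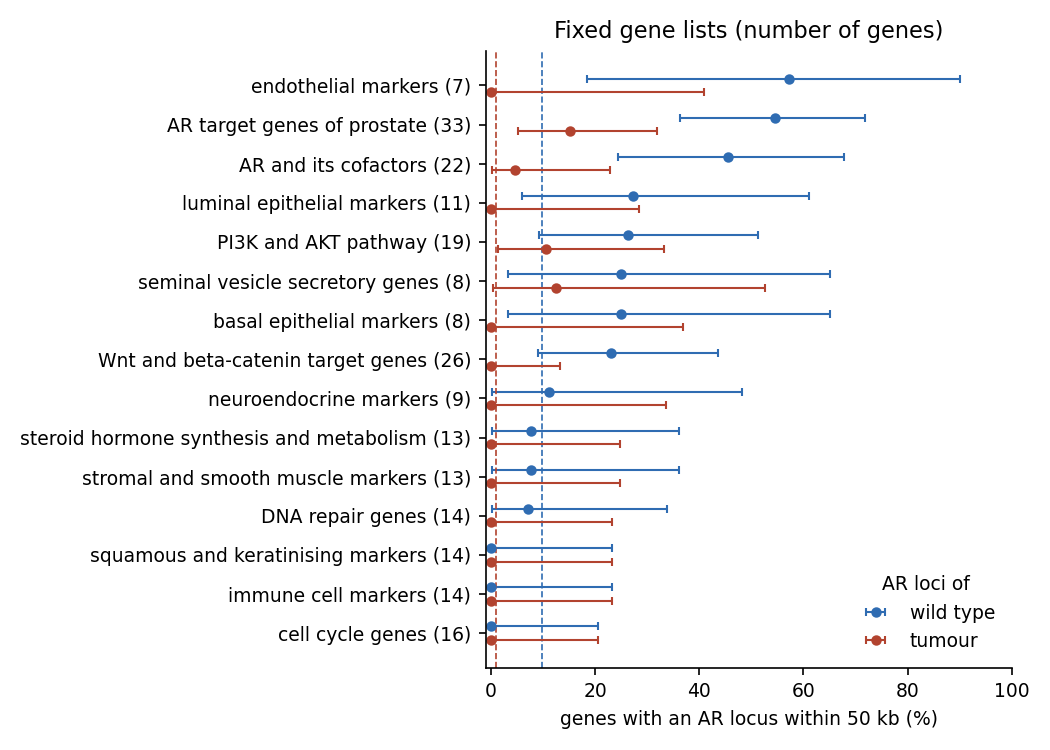
Share of the genes of each of the 15 fixed lists with a wild-type (blue) or tumour (red) AR locus within 50 kb, with 95% Clopper-Pearson intervals, and dashed lines for the mean share of all other genes. AR target genes reach 54.5% in wild type and 15.2% in tumour.

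The authors had named androgen response genes in 41 regions of 22 genes. In the authors' deposited table, 37 of these regions were marked in wild type and 7 in tumour. At Fkbp5 the authors' tumour region (chromosome 17, 28419957 to 28420613, authors' mean fold 13.08) lay inside a region marked in wild type (28419566 to 28420750, fold 24.48). In the authors' deposited table Creld2, Mthfd2 and Pitpnm2 had a region marked in both tissues. The authors' folds in tumour and wild type were 9.31 and 15.19 at Creld2, 8.49 and 9.68 at Pitpnm2, and 12.76 and 8.18 at Mthfd2 (chromosome 6, 83315076 to 83315782). The regions at Creld2 and Pitpnm2 lay inside regions marked in wild type, with authors' folds of 27 and 21.88.

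Wild-type loci favoured gene bodies, with 53.6% inside a protein-coding gene body against a mean of 41.5% (39.8 to 43%) in 100 reshuffles. For tumour loci the share was 44.4%, within the 34.5 to 47.9% of the reshuffles. Tumour loci lay in gene bodies less often than wild-type-only loci did (126 of 284, 44.4%, 38.5 to 50.4%, against 1720 of 3167, 54.3%, 52.6 to 56.1%; Fisher's exact test, BH p = 0.00226). The difference was not called without tumour mouse 1 (-5.41 points, Fisher's exact test, BH p = 0.846), without tumour mouse 3 (-10.1 points on 46 tumour loci, BH p = 0.349) or in the stronger 50% of regions (a difference of -5.26 points, BH p = 0.33). Only 1.41% of tumour loci and 1.74% of wild-type-only loci lay outside a gene body but within 1 kb of one.

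Autosomes carried 1.37 wild-type loci per Mb, from 1.05 on chromosome 14 to 1.85 on chromosome 11. Chromosome X carried 0.246 per Mb (42 loci) and no reproducible tumour locus (Fisher's exact test, p = 0.0456, BH p = 0.13). Chromosome 8 held 29 tumour loci and 170 wild-type-only loci, the only chromosome whose share differed (Fisher's exact test, BH p = 0.0393). The call was lost when the 4 loci wider than 5 kb were left out, in the stronger 50% of regions, and when tumour mouse 1, 2 or 3 or wild-type mouse 1 or 2 was left out.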

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

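The excess of wild-type over tumour loci, the lower tumour MACS folds and the binding of AR target genes kept their direction in all settings run. The alternatives with USeq folds, the mean of both callers, unmerged rows, territory-matched genes, tumour-only loci left out and loci of a single row were chosen after the data were seen. Of all values recomputed, 184 stayed on the same side of their threshold, within their spread or, for counts, within 1.5 times the main count. Many of these could not change: leaving out a mouse cannot alter gene-list shares of the other tissue. Tests between mice cannot give p below 0.1, so 184 overstates stability. Another 53 values moved, among them the chromosome 8 call, which was lost in 7 settings. A further 11 lost their call. Where the cause of a change is not given, the cause was not tested.

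Leaving out each mouse in turn, with both remaining mice of its tissue then required, gave 5.47 to 126 wild-type loci per tumour locus, 56.5 to 90.3% of tumour loci shared and 0.675 to 12.5% of wild-type loci shared. The median log2 difference in MACS fold ran from -1.07 to -0.61, and the share of shared loci with a lower tumour fold from 96.2 to 100%. The excess of tumour loci far from genes ran from 3.39 to 12.5 points and the gene-body difference from -11.8 to -5.41 points, with the call lost without tumour mouse 1 or 3. Without tumour mouse 3 the differences were 9.61 and -10.1 points, near the main values, on fewer loci. The difference in wild-type fold between shared and other loci ran from 0.80 to 6.90, with the call lost without tumour mouse 3. The width difference ran from 132.5 to 330 bp. Endothelial markers ran from 28.6 to 57.1% of genes, 3 to 5 gene lists passed the test, and 0 or 1 chromosomes differed. The share of AR target genes with a wild-type locus ran from 36.4 to 54.5% and with a tumour locus from 6.06 to 15.2%, and that of AR cofactors from 27.3 to 45.5%, all past the threshold.

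Counting a call in any mouse, wild type had 4.98 times the tumour loci, 98.3% of tumour loci were shared and 19.7% of wild-type loci. These values are largely set by the filter of the list. With 50% reciprocal overlap, 78.9% of tumour loci were shared. Among rows as marked by the authors, unmerged, 40.9% of tumour rows and 3.06% of wild-type rows were shared. In the stronger 50% of rows by fold, 91.5% of tumour loci were shared and the median log2 difference was -1.06. The difference in loci far from genes was 4.29 points and that in gene bodies -5.26 points, neither called. AR cofactors fell to 27.3% (still called), endothelial markers to 28.6% (not called), 0 chromosomes differed, and autosomes carried 3.57 times the loci per Mb of X. Without loci over 5 kb, 0 chromosomes differed. With genes within 100 kb, 5 lists passed. With territory-matched genes, 1 list passed: AR cofactors (45.5% of genes) and endothelial markers (57.1%) did not. USeq folds gave a median log2 difference of -0.41 with 73.7% of loci lower in tumour, and the mean of both callers gave -0.72.

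Mouse numbers do not pair the mice by the labels, and the deviations of same-numbered mice correlated at 0.03, -0.16 and 0.04 across loci. With mouse number as a replicate block, the ratio of loci per mouse stayed 8.16, and exact sign flips gave p = 0.25, the smallest that 3 pairs allow. Alternatives for counts, input subtraction, pseudocounts, other thresholds of the authors' own test and motifs were not run, since they need read counts, p-values or a genome sequence, which were not used here. Without read counts, a weaker tumour signal cannot be separated from a shallower library.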

Other observations

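Some genes outside the fixed lists had several loci, and those named here were chosen after their values were seen. Whether loci cluster more than by chance was not tested. Between the Fkbp5 gene body and Armc12 lay 6 wild-type loci, 26007 to 36594 bp beyond Fkbp5, and 3 of them were also reproducible in tumour. The strongest (chromosome 17, 28512156 to 28513437) had MACS folds of 31.5 ± 25.9 (SD, n = 3) in tumour and 50.7 ± 17.6 (SD, n = 3) in wild type, and USeq folds of 23.2 ± 2.07 (SD, n = 2) and 18.4 ± 5.84 (SD, n = 3). By nearest gene they counted for Armc12 and not for Fkbp5. Tns1, an adhesion protein gene, had 7 wild-type loci and no reproducible tumour locus. Aff1 and Zbtb20 had 6 each with no tumour call. These are long genes, of 214 kb (Tns1), 163 kb (Aff1) and 759 kb (Zbtb20), and long genes collect more loci by chance. Gse1 (chromosome 8) was the only gene with 2 tumour-only loci free of any wild-type call (120369931 to 120370403 and 120500818 to 120501452). The second was called in all 3 tumours, with USeq folds of 10.2 ± 4.94 (SD, n = 3), and Gse1 also held 2 loci of wild type alone.

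All tests below except that of regions left out of the table were chosen after the result was seen. Fewer tumour than wild-type loci were listed. Weakness of tumour mouse 2 alone is argued against as the whole cause, since tumour mice 1 and 3 shared 259 loci and the lowest wild-type pair 1553. The authors' removal of shared regions with folds within 10% cannot alter the difference where such a region forms a locus alone. It would then count in both tissues. Where it overlapped a listed region of 1 tissue, its removal would leave that locus counted in 1 tissue, which alters the difference. At Pitpnm2, for example, the region marked in both tissues lay inside a region marked in wild type alone. The removal could also alter the ratio and the shares of loci found in both. The comparison planned for this cannot show by how much. In it, 17 regions marked in both tissues had folds in the band just above that limit, against a set minimum of 312.4 (10% of the difference in loci). A lower sensitivity in the tumour libraries remains open, because tumour calls concentrated at strong wild-type loci (43.1% of the top 10%, against 11.3% of the lower 50%). Lower AR occupancy in tumour cells, or a smaller share of AR-positive cells, would give the same pattern and was not tested.

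Of 169 regions the authors marked in tumour alone, 126 (74.6%, 95% interval 67.3 to 80.9%) overlapped another region marked in wild type. This is consistent with single binding sites having been listed as several regions, and tumour-specific binding read from such regions, as at Fkbp5, would be overstated. No biological explanation was tested for this pattern.

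Tumour-only loci may reflect single libraries more than the tissue. Of the 43, 48.8% (33.3 to 64.5%) were called in tumour mouse 2, the library with the fewest calls, against 11.6% (7.86 to 16.4%) of shared loci (Fisher's exact test, p = 1.17e-07). Their wild-type calls fell in mouse 3 at 24 loci, in mouse 1 at 3 and in mouse 2 at 4. At 15 of the 43, tumour mice 1 and 2 and wild-type mouse 3 had a call and no other mouse did. At most of these 15 the mean fold was higher in wild type, as at Mdga2 (10.05 against 4.24 in tumour). It was lower in wild type at a locus near Pdia4 (3.42 against 3.88) and near Rpusd4 (3.64 against 3.85). The 12 loci without a wild-type call, Myo5b and Gse1 among them, stay open as sites bound in tumour alone, though no list of regions with signal in any library was used here. The weakest of the 12 were a locus in Sfi1 (mean USeq fold 1.93, no MACS call) and a locus 1031707 bp from Lrrc4c (mean MACS fold 4.59, n = 3, no USeq call).

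The gene symbols in the authors' table included Mir3110 at 126 regions, BC002163 at 80 and Eno1b at 61 that lie over 5 kb from, or on another chromosome than, that gene (chosen after their values were seen). Chromosome X carried 5.56 times fewer wild-type loci per Mb than the autosomes. At the locus of Hsd17b3, assigned at 44622 bp, a single tumour had a USeq fold of 26.7, against a mean USeq and MACS fold of 10.3 in wild type.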
